A study of Homo sapiens with 28 samples.

How the data were processed

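RNA was sequenced from hepatocyte-like cells, which are liver-like cells made from human induced pluripotent stem cells. Per the labels, the cultures came from 5 stem cell lines that share the parental line name FSPS13B. Lines 9 and 30 carried wild-type PNPLA3 (WT), lines 6 and 21 a knockout (KO), and line G342 the I148M protein variant of PNPLA3. Each line was differentiated in 2 separate rounds, differentiation 1 and differentiation 2, and a culture below means 1 line in 1 round, so there were 10 cultures. Per the labels' protocols, the differentiation took 30 days, cells were moved on day 23 into 3-dimensional culture in matrigel, grown there for 6 days, and then kept for 24 hours in control medium or in medium with 0.25 mM oleic acid or 0.25 mM palmitic acid. Of the 30 combinations of culture and medium, 28 libraries were used here; the oleic acid libraries of line 9 and line 6 in differentiation 1 are not analysed here.

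Libraries were made with a directional RNA kit, per the labels' protocols. The deposited table gave raw read counts per gene for each library, made by the authors with Subread on GRCh37 (hg19) per the submitters' processing notes; the version, the aligner's settings, read filters and the strand setting of the counting are not given in the sources used here. Where a gene overlaps another gene, or an antisense gene lies on its other strand, counts therefore cannot be assigned with certainty. No column was left without a sample. The table listed 57820 gene identifiers, of which 51996 were matched by identifier to a table of gene names and a further 342 to a gene annotation, 90.5% in all, and the remaining 5482 kept no symbol. The reference at hand was of another genome build than the counts, so no coordinates are given.

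Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter on low counts by group, which left 14586, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 28 libraries with 1 mean for each of the 9 groups of genotype and medium, so that the groups with 2 libraries shared the estimate of spread of the others. Genotypes were compared in control medium. Each fatty acid was compared with control medium, and palmitic with oleic acid, as the mean of the effects in the 3 genotypes. The interaction of genotype and fatty acid was tested with an F test of its 4 terms and then term by term. A gene was called at an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05, and every adjusted p for a gene is from edgeR's quasi-likelihood test unless another tool is named. Levels are in CPM (edgeR's measure of counts relative to the TMM-scaled library size), given as mean ± SD over libraries; log2 CPM used a prior count of 2. The edgeR calls were not made from CPM. It is used for description, for the permutation tests and for the later tests on levels of genes, lists and libraries.

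The labels give each culture the same line and round in every medium. Deviations of log2 CPM from the group means correlated in all 26 pairs of libraries from the same culture (Pearson's r across genes 0.288 to 0.721), so the media are paired by culture. In the I148M groups of 2 libraries the deviations mirror each other, so each r there occurs in both rounds, and the highest r is among them. In the other lines r reached 0.540. Libraries of different genotypes correlated by a median of 0.142 within the same round and by −0.142 between rounds. Fits with the culture as a block for the fatty acid comparisons, and with the round as a block for the genotype comparisons, are therefore given beside the counts of genes, and beside the gene lists described, where they move the count by over 1.5 times. The labels do not name separate starting cultures beyond line and round. A p-value between genotypes rests on the spread of libraries within the 9 groups of all 28 libraries, not on the spread between lines. In control medium WT and KO each hold 4 libraries from 2 lines. I148M rests on 1 line, so that in every comparison with I148M genotype and cell line are not separable. Pairs of lines were also compared with one another, in a fit with 15 groups of line and medium, over the mean of the 3 media.

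The genes named were set by a rule written before the data were examined: PNPLA3; among called genes with a symbol and at least 1 CPM in the higher group, the 8 largest changes in each direction with 1 sign throughout the lines, or in at least 80% of the cultures; then up to 4 called members of each gene list with the smallest adjusted p. Where fewer than 10 genes were called, all of them and the 5 smallest p were taken, and for the interaction the 8 smallest adjusted p. Not every gene the rule gave is printed, and some are not reported here. The 30 gene lists, for pathways, cell states and cell types, were also written before the data were examined. They were tested with camera on limma 3.58.1 voom values at the preset correlation of 0.01 and adjusted over the lists of a contrast; over the 6 main comparisons 49 of 180 list tests passed, against 4 with an estimated correlation. An adjusted p called that of a list is from camera at the preset correlation, and the one with an estimated correlation follows it. Single values were compared with two-sided exact permutation tests.

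Library totals ran from 4743545 to 14747415 counts. A count of 0 in a library allows up to 3 counts, which is 0.203 CPM in the deepest and 0.632 CPM in the shallowest library; this floor covers counting error only. No 2 libraries of a group had counts within sampling noise of each other. The pipeline was tested on simulated counts with 200 changed genes among 14586. The simulated counts held an effect of the culture (SD 0.2 on the log2 scale) but none of the cell line or the round. The shares of false calls below therefore do not cover differences between lines or rounds. For KO against WT it recovered 23.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 2.33% of calls false. For I148M against WT recovery was 8.96%, 56.7% and 87.9%, with 7.27% false. For palmitic acid it was 71.6%, 86.6% and 98.5%, with 2.52% false, and for the difference between KO and WT in the response to palmitic acid 0%, 41.8% and 83.3%, with 1.19% false; with the culture as a block the last became 38.8%, 76.1% and 83.3%, with 6.38% false.

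Alternatives set before the data were examined were edgeR's RLE scaling, DESeq2 1.42.0, no filter on low counts, leaving out each culture in turn, each differentiation alone, limma voom with cell line as a random block, counts summed per line, the mean over the 3 media, only the libraries compared, and the replicate blocks. Fits without 1 library, the I148M control library of differentiation 2, were chosen after seeing the data, as was the count, within each line, of genes under 0.5 CPM in every library of one differentiation and at 5 CPM or more in every library of the other. Figures were drawn with matplotlib 3.10.9.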

Results

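Gene expression was measured by RNA sequencing in hepatocyte-like cells of 3 PNPLA3 genotypes in 3 media, to study how PNPLA3, a lipase of lipid droplets whose I148M variant is linked to fatty liver disease, bears on the response of liver cells to fatty acids. Oleic acid is a monounsaturated and palmitic acid a saturated fatty acid. In control medium there were 4 WT, 2 I148M and 4 KO libraries, with oleic acid 3 WT, 2 I148M and 3 KO libraries, and with palmitic acid 4 WT, 2 I148M and 4 KO libraries. Library totals ranged from 4743545 counts (WT with oleic acid, line 30, differentiation 2) to 14747415 counts (WT with oleic acid, line 30, differentiation 1). Control library totals averaged 9631000 counts in WT and 9576000 in KO.

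PNPLA3 (ENSG00000100344.6), the targeted gene, was measured first. Its level was 46.5 ± 7.84 CPM (SD, n = 11) over all WT libraries, 51.7 ± 8.15 CPM (n = 6) over all I148M libraries and 19.9 ± 4.20 CPM (n = 11) over all KO libraries. The highest KO library, at 26.1 CPM, lay below the lowest WT library, at 37.3 CPM. In control medium PNPLA3 was 0.386-fold in KO relative to WT (log2 −1.37, SE 0.19, adjusted p = 5.95e-05), and an exact permutation test of log2 CPM gave p = 0.0286, the smallest that the 70 assignments of 8 libraries allow. Between I148M and WT the log2 difference was −0.15 (adjusted p = 0.878). Reads from PNPLA3 were thus still counted in every KO library, and gene-level counts do not show which part of the transcript they came from. PNPLA3 passed no test for either fatty acid (log2 0.15 with oleic acid, adjusted p = 0.923, and 0.15 with palmitic acid, adjusted p = 0.682).

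**Figure D1:**
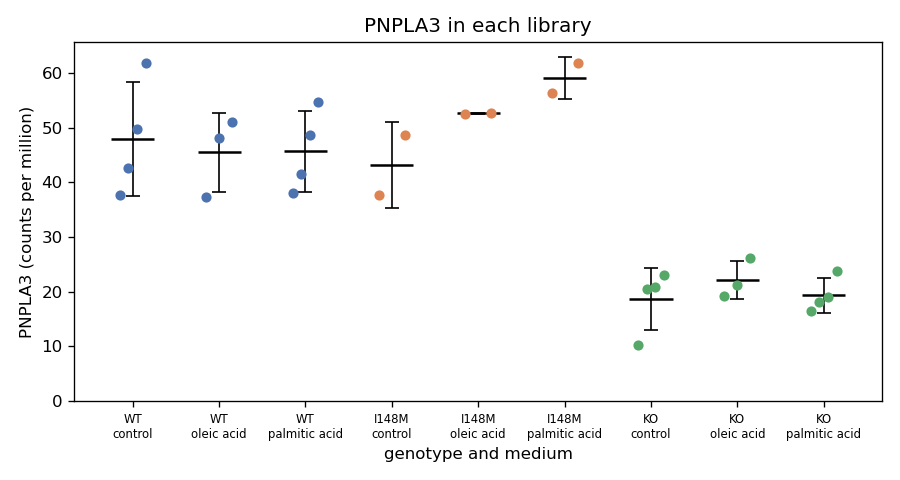
PNPLA3 level in CPM (vertical axis) in each of the 28 libraries (points), by genotype and medium, with the mean and SD of each group. The 11 KO libraries lie between 10.3 and 26.1 CPM and the 11 WT libraries between 37.3 and 61.8 CPM.

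The first comparison asked what loss of PNPLA3 changes in cells kept in control medium. Of the 29 hepatocyte markers tested, 15 were lower in KO and none were higher. FGA, a chain of fibrinogen, was at 8954 ± 563 CPM in KO and 19930 ± 1051 CPM in WT (n = 4 each; log2 −1.15, SE 0.14). ITIH2, an inhibitor chain of plasma, was at 178 ± 63.5 against 709 ± 111 CPM (log2 −1.99), ITIH1 at 69.7 ± 5.34 against 353 ± 84.3 CPM (log2 −2.34), and AMBP at 327 ± 43.8 against 1072 ± 255 CPM (log2 −1.71). Of 11 markers of fetal hepatocytes 6 were lower and none higher, among them IGF2 (8182 ± 1823 against 17900 ± 1863 CPM), GPC3 (1002 ± 90.6 against 1796 ± 94.3 CPM) and CYP3A7, a cytochrome P450 of the fetal liver (0.782 ± 0.190 against 91.0 ± 44.5 CPM).

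Some genes that make, burn and export lipids were lower in KO too. Of 18 genes of fatty acid synthesis and desaturation 8 were lower and none higher, including SCD, which puts the double bond into palmitic and stearic acid (1137 ± 162 against 2051 ± 161 CPM, log2 −0.85), ACSS2 (log2 −1.15), ACLY (log2 −0.81) and GPAM (log2 −0.79). Of 26 genes of cholesterol synthesis and uptake 11 were lower and none higher, including LSS (log2 −1.02), DHCR7 (log2 −0.84) and TM7SF2 (log2 −0.81). Of 29 genes of fatty acid oxidation and PPARA targets 14 were lower and none higher, with HADHB at log2 −0.79, ETFDH at log2 −0.67 and CYP4A11 at log2 −3.65. Of 26 genes of lipoproteins and lipid secretion 12 were lower and 2 higher. LIPC, hepatic lipase, was at 14.7 ± 3.25 against 82.4 ± 7.70 CPM (log2 −2.51), APOB at 7416 ± 1340 against 12940 ± 1274 CPM (log2 −0.80) and APOA5, which raises triglyceride clearance, at 5.03 ± 2.73 against 19.3 ± 5.23 CPM (log2 −2.02). Of 19 genes of bile acid synthesis and transport 6 were lower and none higher, including BAAT, which joins bile acids to amino acids (1.43 ± 1.12 against 45.9 ± 17.4 CPM), AKR1D1 (log2 −1.80) and CYP8B1 (log2 −1.03).

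By camera these lists were lower in KO at an adjusted p of 3.15e-10 for hepatocyte markers, 1.03e-05 for fetal hepatocyte markers, 1.25e-06 for fatty acid synthesis, 3.24e-08 for cholesterol synthesis, 2.78e-09 for fatty acid oxidation, 3.19e-07 for lipoproteins and 6.69e-05 for bile acids. With an estimated correlation none of these passed: the adjusted p was 0.0952 for hepatocyte markers, fetal hepatocyte markers, fatty acid synthesis, lipoproteins and bile acids, 0.161 for cholesterol synthesis and 0.119 for fatty acid oxidation. Adjusted over the list alone, 17 hepatocyte markers were lower and 1 higher, 12 genes of fatty acid synthesis lower and 1 higher, 16 of cholesterol synthesis lower and 1 higher, and 19 of fatty acid oxidation lower and 1 higher. The calls compare 4 libraries from 2 lines on each side, with the spread estimated over all 28 libraries.

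Most other lists of liver genes went both ways, but cytochromes P450 did not. Of 12 cytochromes P450 none were higher and 3 lower, including CYP2C8 (1.03 ± 0.930 against 13.1 ± 2.47 CPM). The list adjusted p was 0.0261, and 0.364 with an estimated correlation. Of 33 conjugating and alcohol or aldehyde enzymes 4 were higher and 7 lower, among the lower UGT2B4 (log2 −1.94) and ALDH1A1 (log2 −0.67). Of 25 NF-kB and acute phase genes 2 were higher and 6 lower, the complement component C3 at 684 ± 138 against 2120 ± 652 CPM and haptoglobin (HP) at 2798 ± 260 against 4791 ± 338 CPM. Of 25 members of the ATF4/CHOP response, a stress pathway, 3 were higher, PPP1R15A (log2 0.67), SLC3A2 (log2 0.63) and ATF4 (log2 0.35), and 1 was lower, PSAT1 (log2 −0.65), against 4 and 3 with the round as a replicate block. Of 24 genes of gluconeogenesis and glycolysis 5 were higher and 4 lower, the lower ones including FBP1 (log2 −1.52) and TAT (log2 −1.44) and the higher ones PGK1 (log2 0.45). None of these last 4 lists passed camera, with adjusted p between 0.12 and 0.653. Counts of CYP3A7, CYP2C8, UGT2B4 and the AKR1C genes are uncertain, since these have near-identical relatives and the counting of shared reads is not given.

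Markers of other cell types were tested as lists as well. Of 9 cholangiocyte (bile duct cell) markers 4 were higher in KO: SOX9 (73.8 ± 10.8 against 38.4 ± 5.97 CPM, log2 0.94), EPCAM (810 ± 111 against 501 ± 45.4 CPM, log2 0.69), ANXA4 (log2 0.71) and SOX4 (log2 0.37), with a list adjusted p of 0.016 and an adjusted p of 0.0952 with an estimated correlation. Of 21 markers of stellate cells and fibroblasts 5 were lower and 1 higher, among the lower DCN (0.182 ± 0.157 against 4.49 ± 3.41 CPM), TIMP1 (84.9 ± 10.9 against 156 ± 7.60 CPM) and ACTA2 (2.88 ± 0.861 against 6.04 ± 2.27 CPM); the list adjusted p was 0.00572, and 0.582 with an estimated correlation. With the round as a replicate block 10 were lower and 2 higher. The list means of log2 CPM in control medium were 8.81 ± 0.16 in KO and 9.51 ± 0.21 in WT for hepatocyte markers, 5.77 ± 0.26 against 5.66 ± 0.14 for cholangiocyte markers and 3.02 ± 0.57 against 4.53 ± 0.54 for stellate markers, with an exact permutation p of 0.0286, 0.514 and 0.0286. Pluripotency markers were low in all libraries: ZFP42 and SOX2 had no count in the 4 KO control libraries and 1.83 ± 0.206 and 1.10 ± 0.659 CPM in WT. FABP2, a fatty acid binding protein of the intestine, was higher (log2 2.05) and TFF2, a gastric peptide, lower (69.5 ± 16.8 against 180 ± 19.4 CPM).

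In all, edgeR called 1913 of 14586 genes between KO and WT, 944 higher and 969 lower in KO, of which 588 differed by over 2-fold. Some of the largest differences were between near absence and presence. LRRC61 was at 0.021 ± 0.042 CPM in KO and 7.78 ± 1.93 CPM in WT, TSPYL5 at 0.059 ± 0.074 and 15.4 ± 0.977 CPM, CRP, an acute phase protein, at 0.047 ± 0.054 and 7.51 ± 4.53 CPM, and CHCHD2, a mitochondrial protein, at 16.5 ± 5.73 and 0.054 ± 0.107 CPM. ZIC4 had no count in the 4 WT control libraries and 2.10 ± 0.336 CPM in KO, and the lens protein genes CRYAA and CRYBA1 had none in KO and 2.60 ± 1.89 and 1.65 ± 0.959 CPM in WT. The difference was recomputed within each differentiation, where it came to 1692 and 2203 genes. Leaving out line 9 of differentiation 2 gave 1249 genes and leaving out line 21 of differentiation 2 gave 1168.

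**Figure D2:**
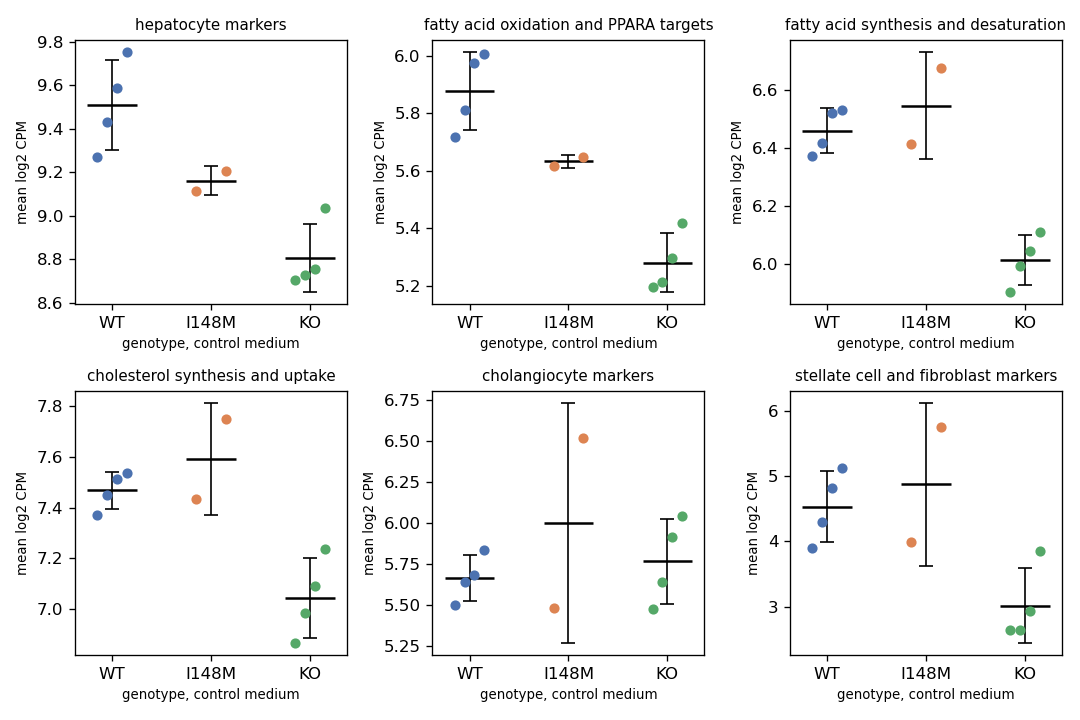
Mean log2 CPM of the tested members of 6 gene lists (vertical axes, each with its own range) in each control library (points) by genotype, with the mean and SD of each group. For hepatocyte markers the 4 KO libraries, at 8.71 to 9.04, lie below the 4 WT libraries, at 9.27 to 9.75, and for stellate cell and fibroblast markers one I148M library lies at 5.76 and the other at 3.99.

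The second comparison asked what differs in the line with the I148M variant. I148M cultures in control medium differed from WT in 98 genes, 63 higher and 35 lower. ZNF253, a zinc finger gene, was at 6.98 ± 0.279 CPM in I148M (n = 2) and 0.027 ± 0.054 CPM in WT (n = 4). C9orf64 and LRRC61 had no count in either I148M control library and were at 9.07 ± 3.63 and 7.78 ± 1.93 CPM in WT. GPRC5B (52.6 ± 14.2 against 194 ± 24.4 CPM, log2 −1.88), DCLK2 (0.368 ± 0.261 against 5.92 ± 0.224 CPM) and PEG10, an imprinted gene of the fetal liver (816 ± 217 against 1862 ± 369 CPM, log2 −1.19), were lower. No member of the lists of fatty acid synthesis, cholesterol synthesis, fatty acid oxidation or lipoproteins was called by edgeR without a block, and no hepatocyte marker was. The genes with an unadjusted p under 0.05 numbered 1629 over all genes tested.

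Several of the larger differences rested on 1 of the 2 I148M control libraries, that of differentiation 2. IGDCC3 (31.3 ± 43.1 against 0.465 ± 0.277 CPM) and the glucose transporter SLC2A1 (429 ± 306 against 172 ± 17.1 CPM, log2 1.32) had an SD above the mean difference. That library also held the highest mean of stellate cell and fibroblast markers, at 5.76 log2 CPM against 3.99 in the I148M library of differentiation 1 and 3.90 to 5.12 in WT; the oleic and palmitic acid libraries of the same culture held 5.04 and 4.88. Without it, a choice made after seeing the data, 42 genes were called, and IGDCC3 and SLC2A1 were not among them. Hepatocyte markers as a list were lower in I148M (adjusted p = 2.46e-06), but not with an estimated correlation (adjusted p = 0.584). With the round as a replicate block the count rose to 344 genes, 199 higher and 145 lower, among them 6 hepatocyte markers, 2 lipoprotein genes and 1 gene of fatty acid oxidation lower, and 1 cholesterol gene higher and 1 lower. A fit of only the libraries compared called 15 genes. Leaving out a culture gave 35 (line 9, differentiation 2), 38 (line 9, differentiation 1), 49 (line 30, differentiation 2), 52 (line 30, differentiation 1), 311 (I148M, differentiation 2) or 472 genes (I148M, differentiation 1).

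The third comparison, of I148M with KO, gave lipid genes that were higher in I148M. Of 18 genes of fatty acid synthesis 7 were higher and none lower, with SCD at 2282 ± 351 CPM in I148M and 1137 ± 162 CPM in KO (log2 1.01), ACSS2 at log2 1.14 and FADS2, a desaturase, at log2 0.79. Of 26 genes of cholesterol synthesis and uptake 10 were higher and none lower, including DHCR7 (log2 0.87) and FDPS (log2 0.66). Of 29 genes of fatty acid oxidation 5 were higher, including PPARA itself (125 ± 22.6 against 78.5 ± 19.2 CPM), of 26 lipoprotein genes 5 were higher, including LIPC (43.9 ± 13.3 against 14.7 ± 3.25 CPM; not called without the I148M control library of differentiation 2), and of 19 bile acid genes 3, including CYP8B1 (log2 1.17). With the round as a replicate block 8 lipoprotein genes were higher. AKR1C1, which NRF2 controls, was at 54.9 ± 16.2 against 19.1 ± 4.39 CPM, IGF2 at 17790 ± 1966 against 8182 ± 1823 CPM, and ITIH2 at 488 ± 110 against 178 ± 63.5 CPM. These lists passed camera, at adjusted p of 3.97e-11 for fatty acid synthesis and 2.77e-14 for cholesterol synthesis, but not with an estimated correlation, at adjusted p of 0.0798 and 0.124.

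Of the stellate cell and fibroblast markers 8 of 21 were higher in I148M than in KO, among them COL1A1 (229 ± 254 against 27.8 ± 14.3 CPM), COL5A1 (663 ± 852 against 62.9 ± 17.8 CPM) and LUM, and outside that list MMP2 (282 ± 386 against 1.79 ± 1.21 CPM) and GABRP (209 ± 289 against 0.754 ± 0.924 CPM); the list adjusted p was 4.31e-05, and 0.32 with an estimated correlation. All of these were not called without the I148M control library of differentiation 2, and COL5A1 then had a log2 difference of −0.05. In all 446 genes were called, 338 higher and 108 lower in I148M, against 147 without that library, 785 with the round as a replicate block and 12 in a fit of only the libraries compared. The count became 970 without I148M of differentiation 1, 208 without I148M of differentiation 2, 261 without line 21 of differentiation 1 and 166 without line 21 of differentiation 2.

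KO and I148M were each set against the same 4 WT libraries. The log2 differences correlated with r = 0.395 across genes, which are not independent replicates, against a mean of 0.403 for 20 simulated pairs of unchanged groups. The covariance was 0.196 against a mean of 0.0727 and at most 0.0835 simulated. The simulated libraries were independent, with no shared effect of line, culture or round. The simulation therefore does not decide whether more than the shared controls lies behind the excess. Of the called genes 25 were higher and 20 lower in both and 0 opposite by edgeR, where independent lists would share 4.08 and 2.33, a number that leaves out the shared controls. With WT line 9 used for one comparison and WT line 30 for the other, the correlation was 0.182 or 0.232, the covariance 0.102 or 0.125, and 2 genes were higher and 3 lower in both, or 7 higher and 6 lower, with 0 opposite by edgeR.

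Since genotypes were represented by few lines, lines were also set against one another over the mean of the 3 media. This fit took the correlated libraries of a culture as independent, so its counts may be too high. Lines of 1 genotype differed in 15 genes (WT lines 9 and 30) and 16 genes (KO lines 6 and 21). The 4 pairs of a KO and a WT line differed in 1689 to 2638 genes, the I148M line differed from the WT lines in 134 and 301 genes and from the KO lines in 1158 and 1885. With the round as a replicate block these were 25 and 20 within a genotype, 2558 to 3557 between a KO and a WT line, 495 and 773 between I148M and WT lines, and 1987 and 2798 between I148M and KO lines. The largest differences between genotypes included genes with presence in one line and near absence in another: CHCHD2 had a mean of 0.043 and 0 CPM in the WT lines and 20.1 and 11.2 CPM in the KO lines.

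The 2 differentiations of the I148M line were not alike, which was looked at only after the data were seen. Genes under 0.5 CPM in every library of one differentiation and at 5 CPM or more in every library of the other numbered 16 in the I148M line, against 0 in lines 9, 30 and 6 and 1 in line 21. All 16 were present in differentiation 2 in all 3 media, among them CHCHD2 (26.3 to 30.7 CPM against 0 to 0.109), TXNRD2 (7.86 to 8.43 against 0.092 to 0.109) and HAND1, a gene of mesoderm (5.72 to 32.0 against 0 to 0.092). The n of 2 of the I148M groups therefore joins cultures that differ by more, in this count, than the 2 differentiations of any other line, and the cause is not known from these data.

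**Figure D3:**
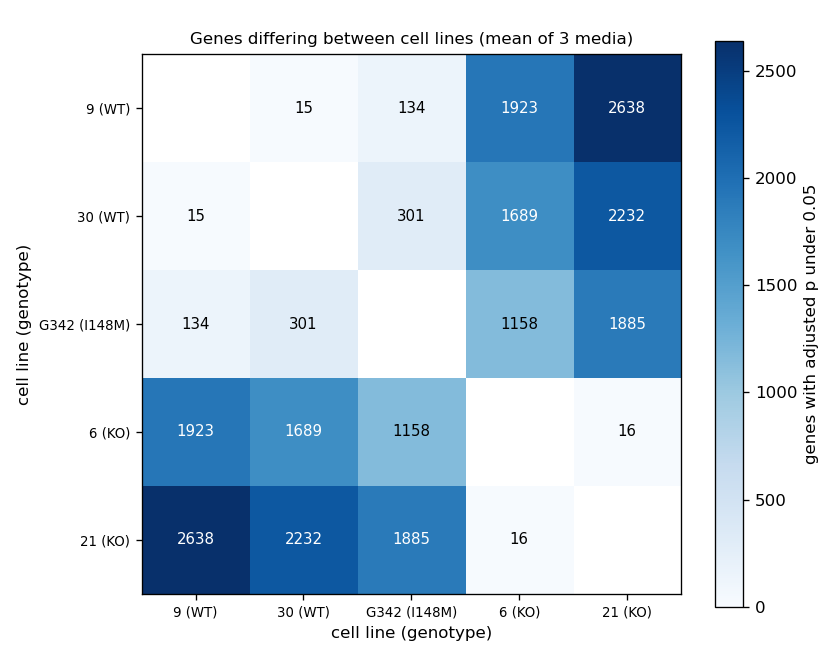
Number of genes with an adjusted p under 0.05 (colour and printed number) between each pair of the 5 cell lines, as the mean over the 3 media. The pairs within a genotype hold 15 and 16 genes, and the 4 pairs of a KO and a WT line hold 1689 to 2638.

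The next comparison asked what oleic acid changes. HADHA, an enzyme of fatty acid oxidation, rose and was 1 of 2 genes called by edgeR, both higher. It rose by 0.33 on the log2 scale (SE 0.05, adjusted p = 0.027), in 8 of 8 cultures that had both media. In WT cultures HADHA was at 299 ± 8.41 CPM (n = 4) in control medium and 381 ± 23.3 CPM (n = 3) with oleic acid, and in KO at 231 ± 15.4 (n = 4) and 269 ± 7.32 CPM (n = 3). FADS2 and ETFDH had log2 differences of 0.43 and 0.41, also in 8 of 8 cultures, at an adjusted p of 0.107, and passed with the culture as a replicate block (adjusted p = 3.58e-06 and 6.49e-05). As a list, fatty acid oxidation and PPARA targets were higher (adjusted p = 1.7e-14), as were genes of cholesterol synthesis (1.74e-08), while proliferation genes were lower (1.18e-11); with an estimated correlation the adjusted p was 0.212, 0.301 and 0.375. Adjusted over the list alone, 8 of 29 genes of fatty acid oxidation, 3 of 26 of cholesterol synthesis and 4 of 20 lipid droplet proteins rose, and 0 of 25 proliferation genes fell by edgeR without the block.

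With the culture as a replicate block edgeR called 428 genes for oleic acid, 191 higher and 237 lower, in place of 2. These held 13 higher genes of fatty acid oxidation, 6 of cholesterol synthesis, 4 lipid droplet proteins and 19 lower proliferation genes of 25. Without the I148M control library of differentiation 2 the counts were 0 without the block and 80 with it. A fit of only the libraries compared called 0 genes. The count of 2 became 0 without line 9 of either differentiation, line 30 of differentiation 2, I148M of differentiation 2, line 6 of differentiation 2 or line 21 of either differentiation, 1 without line 6 of differentiation 1, 4 without line 30 of differentiation 1 and 15 without I148M of differentiation 1.

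Palmitic acid at the same dose and time raised stress genes in every culture. CHAC1, which breaks down glutathione, rose by 3.59 on the log2 scale (SE 0.21, adjusted p = 2.13e-11), the transcription factors ATF3 by 3.14 (SE 0.19) and DDIT3 (CHOP) by 2.32 (SE 0.14), and PPP1R15A by 1.22. The chaperone HSPA5 (BiP) rose by 1.15 (SE 0.08, adjusted p = 1.59e-10), from 898 ± 64.1 to 2887 ± 182 CPM in WT (n = 4 each), and HERPUD1 by 1.77, SDF2L1 by 1.11 and DNAJB9 by 1.11. Each of these 8 genes rose in 10 of 10 cultures. Of 20 ER chaperones and ATF6/XBP1 targets 15 rose and none fell (list adjusted p = 1.96e-37), and of 25 ATF4/CHOP genes 16 rose and none fell (adjusted p = 5.33e-36); these calls held with an estimated correlation, at adjusted p of 8.06e-05 and 1.45e-05. The heat shock gene HSPA6 rose from 1.31 ± 0.424 to 25.2 ± 11.4 CPM in KO, and its log2 change over the genotypes was 5.16, but it shares near-identical sequence with HSPA7 and both values are uncertain. ARC rose by 4.21 and the zinc finger gene ZNF165 by 2.99.

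Inflammatory and lipid genes changed too with palmitic acid. Of 25 NF-kB and acute phase genes 8 rose and none fell, including CXCL1 (2.41 on the log2 scale), CXCL3 (2.13) and TNFAIP3 (1.33); the list adjusted p was 1.77e-07, and 0.325 with an estimated correlation. Of 20 lipid droplet proteins 3 rose, PLIN2 by 0.78, CIDEC by 0.63 and CIDEB by 0.50 (list adjusted p = 0.0111, and 0.257 with an estimated correlation). PNPLA8, a phospholipase of the same family as PNPLA3, rose by 0.52, PCK1, an enzyme of gluconeogenesis, by 1.74 and ELOVL5 by 0.58. Among genes that fell were the cell cycle kinase PBK (log2 −1.05), TYMS (log2 −0.45) and ELOVL6, which lengthens palmitic acid (log2 −0.36). Of 25 proliferation genes 1 fell over all genes tested, 17 fell adjusted over the list alone, and the list adjusted p was 3.69e-11, or 0.325 with an estimated correlation.

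In all 427 genes were called for palmitic acid, 380 higher and 47 lower, and 76 changed by over 2-fold. With the culture as a replicate block the count was 1966, 1059 higher and 907 lower, with 15 NF-kB genes and 5 lipid droplet proteins higher and 22 proliferation genes lower. Without I148M of differentiation 2 it was 160. The fatty acids shared the control libraries, and their log2 changes correlated with r = 0.389 across genes, below the mean of 0.465 simulated for unchanged groups, with a covariance of 0.0283 against 0.0326. The simulation held no effect of the culture, which the media share, so it does not show that a shared response is absent. With the culture as a replicate block 88 called genes were higher and 107 lower with both fatty acids, and 15 opposite. Independent lists would share 13.9 and 14.7, which leaves out the shared controls. Between cultures of different differentiations, which share no library, r was 0.075 and 0.019. There edgeR called 0 genes in the same direction with oleic acid of differentiation 1 and palmitic acid of differentiation 2, and, the other way round, 6 higher in both, 0 lower in both and 7 opposite.

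The direct comparison of palmitic with oleic acid addressed whether the saturated and the unsaturated fatty acid act differently. Stress genes were higher with palmitic acid: HSPA5 by 1.17 on the log2 scale, HERPUD1 by 1.73, DDIT3 by 2.29, ATF3 by 3.07 and CHAC1 by 3.46, each in 8 of 8 cultures. Of 20 ER chaperones 15 and of 25 ATF4/CHOP genes 15 were higher and none lower (list adjusted p = 3.1e-41 and 1.29e-36, and 4.53e-05 and 1.2e-05 with an estimated correlation). NFKBIA (log2 0.86), TNFAIP3 (log2 1.22) and the chemokine CCL2 (log2 2.17) were among 8 of 25 NF-kB and acute phase genes that were higher, with a list adjusted p of 5.63e-08, and of 0.629 with an estimated correlation. The sterol genes FDPS (log2 −0.41) and LSS (log2 −0.32) were lower with palmitic acid, and so was LPCAT1, which remodels phospholipids (log2 −0.54). Of 18 genes of fatty acid synthesis 1 was higher, ELOVL5 (log2 0.72), and 1 lower, ELOVL6 (log2 −0.44; list adjusted p = 0.167). Of 26 cholesterol genes 4 were lower and 1 higher (list adjusted p = 0.00443, and 0.629 with an estimated correlation). HADHA was lower by −0.25. In all 457 genes were called, 379 higher and 78 lower with palmitic acid, and 1704 with the culture as a replicate block, where 14 NF-kB and acute phase genes were higher, 2 cholesterol genes higher and 7 lower, and 1 gene of fatty acid synthesis higher and 5 lower. The count was 174 without I148M of differentiation 2, 300 without line 21 of differentiation 2 and 301 without line 30 of differentiation 2.

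The last question was whether the response to a fatty acid depends on genotype. The stress response to palmitic acid was smaller in KO than in WT. DDIT3 rose by 3.15 on the log2 scale in WT, from 10.2 ± 1.49 to 91.3 ± 6.26 CPM, and by 1.47 in KO, from 11.4 ± 2.40 to 31.2 ± 9.48 CPM, a difference of −1.68 (adjusted p = 0.00388). HSPA5 rose by 1.69 in WT and 0.70 in KO, a difference of −0.98 (adjusted p = 0.00336), and ATF3 by 4.10 and 2.05, a difference of −2.05 (adjusted p = 0.00969). NR4A1, an immediate early gene, reached 58.2 ± 13.6 CPM in WT and 13.5 ± 3.54 CPM in KO, from 4.31 ± 0.587 and 5.99 ± 2.04 CPM. Of 38 genes whose response to palmitic acid differed between KO and WT, all 38 had the lower log2 change in KO. A higher control level in KO also lowers that change, as for PPP1R15A (log2 0.67 in control medium). The count therefore does not show a weaker induction for each gene. Among them were 4 of 20 ER chaperones (list adjusted p = 6.41e-16) and 5 of 25 ATF4/CHOP genes (9.6e-16), which held with an estimated correlation, at adjusted p of 0.0102 and 0.00314. With the culture as a replicate block 9 ER chaperones and 13 ATF4/CHOP genes had the lower log2 change in KO.

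In I148M the log2 changes of these genes lay between those of WT and KO: 2.35 for DDIT3, 1.05 for HSPA5 and 3.25 for ATF3. The 2 I148M cultures differed: the ER chaperone list changed by 0.35 in differentiation 1, within the KO range of 0.23 to 0.60, and by 0.84 in differentiation 2, within the WT range of 0.79 to 0.93, while the ATF4/CHOP list changed by 0.75 and 0.91, both between the KO range of 0.51 to 0.62 and the WT range of 1.16 to 1.27. No gene passed the test of the difference between I148M and WT in the response to palmitic acid by edgeR, where 484 genes had an unadjusted p under 0.05 and DESeq2 called 3, and the ER chaperone and ATF4/CHOP lists passed it (adjusted p = 9.33e-07 and 4.74e-05) but not with an estimated correlation (adjusted p = 0.241 for both). For oleic acid the tests of KO and of I148M against WT called 0 genes by edgeR, by DESeq2 and by limma, with 376 and 259 genes at an unadjusted p under 0.05. The F test over all 4 interaction terms called 20 genes, with DNAJB1, PPP1R15A, MAFF, SELENOK and MIS12 at an adjusted p of 0.00198. For these 5 the KO minus WT term of palmitic acid was −1.20, −1.38, −1.28, −1.55 and −1.03, and the I148M minus WT term was −0.87 for DNAJB1, −0.95 for PPP1R15A, −0.93 for MAFF and −0.52 for MIS12. With the culture as a replicate block the difference between KO and WT for palmitic acid held 373 genes, 78 higher and 295 lower, that between I148M and WT 127 for palmitic and 15 for oleic acid, and the F test called 260. The F test's count was 7 and 6 without line 9 of differentiation 1 and 2, 5 without line 30 of differentiation 2, 12 and 11 without line 6, and 10 and 8 without line 21 of differentiation 1 and 2.

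**Figure D4:**
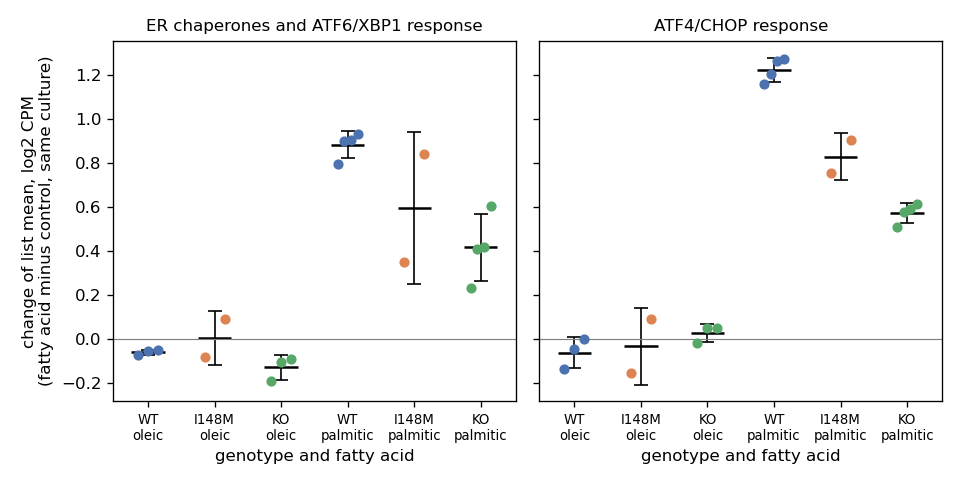
Change of the mean log2 CPM of 2 stress gene lists (vertical axis) from control medium to oleic or palmitic acid in the same culture (points), by genotype, with the mean and SD of each group. With palmitic acid the 4 WT cultures lie between 1.16 and 1.27 for the ATF4/CHOP list and the 4 KO cultures between 0.51 and 0.62.

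Within each genotype, palmitic acid changed 586 genes in WT, 16 in I148M and 12 in KO, and 2074, 358 and 200 with the culture as a replicate block. Against oleic acid it changed 397, 23 and 9, and 1177, 138 and 116 with the block. The 12 genes in KO were all higher and included CHAC1 (log2 2.93), ATF3 (log2 2.05), DDIT3 (log2 1.47), HERPUD1 (log2 1.20) and HSPA5 (log2 0.70). Oleic acid alone changed 0 genes in each genotype by edgeR, with 381, 501 and 717 genes at an unadjusted p under 0.05 in WT, I148M and KO; DESeq2 called 0, 0 and 8, limma 0 in each, and edgeR with the culture as a replicate block 6, 234 and 86. Without the I148M control library of differentiation 2 the 234 fell to 1. Between genotypes in the same fatty acid, KO differed from WT in 1179 genes with oleic and 2000 with palmitic acid. I148M differed from WT in 16 and 56 genes, or 37 and 167 with the round as a replicate block, and from KO in 491 and 493, or 1040 and 966 with that block. In oleic acid the block raised the KO count to 1865.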

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

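The tests of a smaller share of hepatocyte-like cells, of a higher level of stress genes before treatment, of a weaker exposure, of a library of another cell line and of an exchange of wells were chosen only after the results they bear on were seen, and so were the 1 CPM minimum for testing a group for a stray library, the counting of a swap of media and its mirror as 1, and the rule by which the test of mesenchymal cells was read.

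Of 29 hepatocyte markers 15, of 18 genes of fatty acid synthesis 8 and of 26 genes of cholesterol synthesis 11 were lower in KO than in WT control cultures and none higher, and with an estimated correlation the lists did not pass (adjusted p = 0.0952, 0.0952 and 0.161). A smaller share of hepatocyte-like cells, with the mix of the other cells unchanged, would raise the markers of all other cell types alike. Cholangiocyte markers changed by 0.10 (exact permutation p = 0.514) and stellate markers by −1.52 (p = 0.0286) on the log2 scale. The exact permutation p of the difference was 0.0286, the smallest that 70 assignments allow. The values go against such an even shift only. A smaller share with a changed mix of other cells stays open, since the cholangiocyte markers SOX9, EPCAM, ANXA4 and SOX4 were higher in KO. Depth is excluded, since 14 of the 15 lower hepatocyte markers were still lower when all libraries were thinned to 4744000 counts. From the 8 control libraries alone 1715 genes were called, against at most 23 in the other 34 of 35 splits, and that split parts the differentiations. These splits exchange libraries freely across lines and rounds, so they exclude chance among libraries only. Lines stay whole in only 2 of the other splits, which called at most 0 genes. That is too few to exclude chance at the level of the line. The 2 pairs of lines within a genotype held 15 and 16 genes against at least 1689 between a KO and a WT line. An effect of the knockout stays a hypothesis beside a changed mix of cells. Other differences that arose between the WT and KO lines cannot be excluded with 2 lines of each.

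The stress response to palmitic acid was smaller in KO. The mean change of the ER chaperone and ATF4/CHOP lists was 1.07 ± 0.056 in the 4 WT and 0.504 ± 0.084 in the 4 KO cultures. With the culture as a block 276 genes were called, against at most 2 in the other 34 of 35 splits of the 8 cultures. This excludes chance among cultures taken as exchangeable, but not among the 4 lines they came from. A higher level before treatment is excluded for the lists as a set, since their control level in KO was −0.0504 (SE 0.0375) relative to WT against a shortfall of 0.57, though PPP1R15A, SLC3A2 and ATF4 were higher in KO control cultures. A weaker exposure of KO cultures stays open: the response of fatty acid oxidation genes to oleic acid in KO (0.149 ± 0.108, n = 3) exceeded the share expected under it by 0.0391 (SE 0.0657), which cannot be told apart from no excess. That the knockout lowers the response is a hypothesis that these 4 lines do not decide.

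The I148M culture of differentiation 2 held higher levels of some mesenchymal genes, most in its control library. There 10 of 21 stellate cell and fibroblast markers were higher than in each of the 9 other control libraries. COL5A1 was at 1266 CPM there and at 391 and 414 with oleic and palmitic acid, against at most 93.9 in other controls. The other markers were not higher, among them DCN (1.47 against up to 9.40 CPM in other controls) and ACTA2 (2.57 against up to 9.07). Genes outside the mesenchymal sets differed too: TFAP2A was at 5.44 to 33.3 CPM in the libraries of this culture and at 0 to 0.368 in those of differentiation 1. The name mesenchymal thus covers only part of the difference. The values go against a library of another of these cell lines under this label, by a test chosen afterwards that rests on few genes. Of the genes off or on in the other 2 libraries of the culture and the reverse in every library of line 9, 30, 6 or 21, it was as its own culture for 6 of 6, 5 of 5, 12 of 14 and 13 of 15, and as the other line for none. An exchange of the control and palmitic acid wells of that culture would make the changes of its stress lists with palmitic acid negative. The ER chaperone and ATF4/CHOP lists changed by 0.84 and 0.91. An exchange of the control and oleic acid wells would make the change of its fatty acid oxidation list with oleic acid negative, and that list changed by 0.518. The values thus go against each exchange, for oleic acid by 1 list only. The test of a mislabelled sample did not decide. It was written before its outcome was seen, but for a library picked out from these data. The library lay on the I148M side for 54.1% of 85 genes that separate I148M from WT and KO, between the bounds set for and against a mislabelling. The share was 89.4% for the other I148M control library and at most 16.5% for WT and KO controls. A sample from another culture of the same line, outside the libraries used here, was not tested. Mesenchymal cells in that culture well stay open too: 8 of 18 further mesenchymal genes were higher than in each other control library (44.4%, exact interval 21.5% to 69.2%). That met a bound of a share under 0.5, written before this share was seen, but the interval spans it. The rule was changed afterwards to ask that the interval exclude 0.5.

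For KO against WT with palmitic acid 2040 genes were called, and at most 0 in the 34 other splits. This excludes chance among libraries taken as exchangeable, but not among the few lines they came from. For KO against WT with oleic acid 10 splits are too few, with 985 genes and 0 at most in the others. For the fatty acids without the pairing, chance is not excluded: 405 genes for palmitic acid against up to 966 (9 of 100 splits as large), 0 for oleic acid against up to 995 (100 of 100), 391 for palmitic against oleic acid against up to 1196 (5 of 100), and within WT 771 against 816 and 369 against 1011 (2 of 35 each) and within KO 4 against 927 (3 of 35) and 0 against 1554 (35 of 35). In each of these 4 within-genotype comparisons the highest other split parts the differentiations and calls more genes than the real one, which points to a structure of the samples by differentiation. With the culture as a block and media swapped within cultures, which keeps that structure level, chance is excluded: 1669 genes against at most 546 for palmitic acid, 455 against at most 118 for oleic acid and 1974 against at most 937 for palmitic against oleic acid, in 1 of 50 swaps each. For oleic acid this rests on all libraries: without the I148M control library of differentiation 2 the blocked count fell from 428 to 80, for which no swaps were drawn.

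The response to palmitic acid differed between KO and WT by a test of the difference, on the log2 scale, for PPP1R15A (−1.38), ATF4 (−0.80), ATF3 (−2.05), ZNF165 (−2.15), ELOVL5 (−0.96), HERPUD1 (−1.14), HSPA5 (−0.98), SDF2L1 (−1.11), DDIT3 (−1.68), DNAJB1 (−1.20), MAFF (−1.28), SELENOK (−1.55), MIS12 (−1.03), NR4A1 (−2.58), IFRD1 (−1.17) and KLF4 (−1.21), for the ER chaperone list (−0.3741, adjusted p = 0.0102 with an estimated correlation) and the ATF4/CHOP list (−0.719, adjusted p = 0.00314), and in 38 genes in all, with 20 genes in the F test over the 4 terms. KLF4 stood at 17.3 ± 3.40 CPM in WT and 45.1 ± 5.74 CPM in KO control cultures and at 47.0 ± 2.36 and 53.3 ± 6.72 CPM with palmitic acid, so that its difference lies in the control level.

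A library lay far from the 3 others of its group, by the share of the group's range that separates it from its neighbour, in 35 of 779 groups tested (4.49%), where chance gives about 1 in 20. In WT control cultures these were line 30 of differentiation 1 for CRYBA1 (0.858), ETFDH (0.862), FBP1 (0.869), ENG (0.863), CIDEB (0.970), all low, and DACT2 (0.838, high), and line 30 of differentiation 2 for DHCR7 (0.905, low). In WT with palmitic acid they were line 9 of differentiation 2 for muscle markers (0.958, high), line 9 of differentiation 1 for ZFP42 (0.884, high) and CCDC198 (0.975, low), line 30 of differentiation 2 for PSAT1 (0.868, low), HERPUD1 (0.834, high) and RELB (0.981, high), and line 30 of differentiation 1 for NDUFS1 (0.905, low), LOX (0.921, high) and UGT2B11 (0.878, high). In KO control cultures line 6 of differentiation 2 was high for the lipoprotein list (0.839), the hepatocyte list (0.853), NKX2-5 (0.888), APOA4 (0.838) and SDF2L1 (0.830), line 21 of differentiation 1 was low for PNPLA3 (0.850), CREB3L3 (0.852) and DDIT3 (0.834) and high for CXCL1 (0.922) and RPL23AP82 (0.890), and line 6 of differentiation 1 was low for PPP1R15A (0.852). In KO with palmitic acid line 6 of differentiation 1 was low for the ATF4/CHOP list (0.930), HSPA6 (0.971), CHAC1 (0.933), C11orf96 (0.888) and ATF3 (0.869), line 6 of differentiation 2 was low for SDHA (0.833) and high for CIDEC (0.866), and line 21 of differentiation 2 was low for NDUFV1 (0.835).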

How the results depend on the processing

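The alternatives without the I148M control library of differentiation 2 were chosen after seeing the data. Each I148M group holds 2 libraries of 1 line, and with 1 of them left out the other is taken to vary like the other groups. The cause of a change below was not tested unless it is named.

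With no low-count filter 767 genes were called for I148M against WT, 1045 for I148M against KO, 147 for oleic acid, 717 for palmitic acid and 235 in the interaction. With the round as a replicate block the counts were 344 for I148M against WT and 785 for I148M against KO, and with the culture as a replicate block 428 for oleic acid, 1966 for palmitic acid, 1704 for palmitic against oleic acid and 260 in the interaction. In differentiation 1 only, where fewer libraries were used, they were 847 for I148M against WT, 0 for oleic acid, 239 for palmitic against oleic acid and 0 in the interaction. In differentiation 2 only they were 708 for I148M against WT, 1233 for I148M against KO, 93 for oleic acid, 763 for palmitic acid, 693 for palmitic against oleic acid and 47 in the interaction. Counts summed per cell line gave 457 for I148M against WT and 692 for I148M against KO. The mean over the 3 media gave 4844 for KO against WT, 929 for I148M against WT (1509 with the round as a replicate block) and 2859 for I148M against KO. It uses more libraries but no more cultures. The fit took the correlated libraries of a culture as independent, so these counts may be too high. Only the libraries compared gave 15 for I148M against WT, 12 for I148M against KO and 0 for oleic acid. DESeq2 gave 227 for I148M against WT, 51 for oleic acid and, by its likelihood ratio test, 47 in the interaction; it set no adjusted p for 9049 genes with oleic acid, 2828 with palmitic acid and 4242 in their comparison. Of the gene list tests 4 passed with an estimated correlation, against 49 at the preset one.

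Without the I148M control library of differentiation 2 the counts were 42 for I148M against WT, 147 for I148M against KO and 0 for oleic acid. With a replicate block as well they were 2965 for KO against WT, 154 for I148M against WT, 80 for oleic acid, 1107 for palmitic acid, 1767 for palmitic against oleic acid and 207 in the interaction. COL5A1 and L1TD1, higher in I148M than in KO, had log2 differences of −0.0521 and −0.1134 without that library, and leaving out each culture in turn gave −0.0519 to 4.327 for COL5A1 and −0.1082 to 4.9551 for L1TD1.

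Leaving out each culture in turn gave 1168 to 2292 genes for KO against WT, 35 to 472 for I148M against WT, 166 to 970 for I148M against KO, 0 to 15 for oleic acid, 160 to 431 for palmitic acid, 174 to 453 for palmitic against oleic acid and 5 to 30 in the interaction. RLE scaling moved none of the 7 counts by over 1.5 times (1861, 100, 446, 2, 410, 447 and 20 genes in the order of the comparisons). Over the genes the naming rule gave and all alternatives, 4967 results kept their side of the threshold, 803 no longer passed, 14 came to pass and 4 reversed. A change of direction was counted only where the gene was called in the main fit or in the alternative. Among those genes the round as a replicate block changed 0 of 176 calls and the culture as a replicate block brought 3 of 98 past the threshold.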

Other observations

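The count of genes absent in one differentiation and present in the other was chosen only after the data were seen.

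Interferon-stimulated genes as a list were lower in I148M than in WT control cultures (adjusted p = 0.000684), but not with an estimated correlation (adjusted p = 0.584). In KO control cultures 2 of 17 genes of the hypoxia response were higher than in WT and none lower, EGLN3 by 0.70 on the log2 scale and LOX by 0.81 (list adjusted p = 0.0129, and 0.191 with an estimated correlation), and 4 were higher with the round as a replicate block. Of 30 nuclear-encoded genes of oxidative phosphorylation 3 were lower in KO. PNPLA3 and PNPLA8 belong to 1 family, and PNPLA8 rose with palmitic acid while PNPLA3 passed no test with it.

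The 16 genes that were absent in differentiation 1 and present in differentiation 2 of the I148M line include some that also parted WT from KO lines: CHCHD2 was near absent in both WT lines and present in both KO lines, and TXNRD2 had line means of 8.44 and 9.51 CPM in WT and 0.232 and 0.306 CPM in KO. Another, SLC15A4, was near absent in both WT lines, at 9.45 CPM in KO line 6 and at 0 CPM in KO line 21. Over the 3 media 0 genes of this kind differed between the WT lines and 1 between the KO lines, against 3 to 8 for each pair of a KO and a WT line. Whether the 2 I148M differentiations began from the same stock of cells was not tested and is not given in the labels.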
